A study of Zea mays with 9 samples.

How the data were processed

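Total RNA was extracted by the authors from maize seedlings of 3 genotypes (B73, P1-ww714/B73 and P1-ww714), 3 samples each, and libraries were made with standard Illumina protocols, per the labels' protocols. Whether messenger RNA was selected is not given in the sources used here. The deposited table holds raw whole-number counts per gene for 39656 gene identifiers, 1 column per library, and per the labels' processing notes TopHat and HTSeq were used, without versions. The genome build, the annotation, the strand setting and the treatment of reads shared between similar genes are not given in the sources used here, so counts of near-identical paralogs and of overlapping or antisense genes are uncertain. All 9 columns were mapped to the labelled samples by their names. Library totals ran from 9486044 to 16189684 counts, and 9391 identifiers had 0 counts in every library. Pairwise chi-square values per gene between replicates of a group ran from 6.72 to 19.67, so no pair of libraries agreed within sampling noise.

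Names and the order of neighbouring genes came from a reference table for assembly Zm-B73-REFERENCE-NAM-5.0. It matched 18775 identifiers (47.3% of identifiers, holding 82.2% of counts), of which 18756 had a single chromosome and 2652 had a symbol. Since the authors' build is not known, no coordinates are given and the order of genes is that of this assembly.

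Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10), which left 22544 genes, 15703 of them placed and 6841 not placed. TMM scaling and the quasi-likelihood F test were applied to all 9 libraries, and p-values were adjusted by Benjamini-Hochberg at 0.05. Comparisons between genotypes came from 1 fit and share 1 estimate of the spread. The slope over alleles came from a separate fit with its own estimate of the spread. The comparisons were P1-ww714 against B73, P1-ww714/B73 against B73, P1-ww714 against P1-ww714/B73, the heterozygote against the mean of the parents on the log2 scale, and a slope over 0, 1 and 2 alleles. Standard errors and 95% intervals came from the fitted fold and its F value. CPM values were scaled by TMM.

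The segment was the contiguous run of tested chromosome 1 genes with the largest sum of log2 fold minus 0.5, with folds limited to -1 to 2, over genes at even positions. Values were read from the 65 genes at odd positions inside the bounds. Bounds set on the odd positions gave 125 genes, all within the 131. Dose expectations are log2 of 4/2, 3/2 and 4/3. Medians carry bootstrap intervals from 10000 draws over genes. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry.

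The comparisons, their tests, the segment rule, the rule for named genes and the alternatives were fixed before the data were examined, with these exceptions. TMM without the segment for gene counts, an estimated correlation for the segment, DESeq2 for the segment calls, leaving out libraries for the lists, the window of 100 neighbours with its alternatives, the flanks of 300 genes, the overlap by rank and the tests of explanations other than the splits of the libraries were chosen afterwards. The named genes were p1, the 12 segment genes past the threshold with the highest mean expression and a symbol, up to 10 rises and falls per comparison outside the segment with a symbol, average log2 CPM of at least 1 and no overlap between libraries, and list members past the threshold. Genes without a symbol are given for at most 2 rises and 2 falls. Most lists had been defined by words of gene descriptions, which the reference table does not hold, so 16 of 20 lists were matched on symbols instead, before any fold change was computed. Lists of glutathione transferase, oxylipin and jasmonate, water channel, cytokinin and auxin genes were added at that time. Symbol matches can take in genes of other functions. Lists for plastid ribosomal proteins, disease resistance proteins and organelle transcripts could not be matched and were not used here. The 18 lists with at least 3 tested members were tested.

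The procedure was tested on simulated counts for the 22544 genes with 200 changed genes. In P1-ww714 against B73, 17.9% of genes simulated at 1.5-fold, 62.7% at 2-fold and 87.9% at 4-fold were called, and 8.97% of calls were unchanged genes. The segment search recovered 99.2% of a simulated run, the median of the simulated segment genes was 0.97, and 95.4% of the intervals held the simulated fold. In P1-ww714/B73 against B73 the simulated segment median was 0.57.

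Alternatives were RLE size factors, DESeq2 1.42.0, no expression filter, the replicate number as a block, only the groups compared, TMM without the segment, an average log2 CPM of at least 3, a threshold of 0.01, lists without segment genes, and leaving out each library.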

Results

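RNA was sequenced from maize seedlings aged 14 days to compare transcript levels, in 3 genotypes with 3 libraries each. B73 is the reference inbred line of maize. P1-ww714 is an allele of p1, a gene of chromosome 1 that encodes a MYB regulator of red phlobaphene pigments. The genotypes were B73, P1-ww714 and the heterozygote P1-ww714/B73, read here as holding 0, 2 and 1 P1-ww714 alleles. The label P1-ww714 does not itself state that the allele is homozygous. Background knowledge of the study, which the labels do not state, is that P1-ww714 carries a tandem duplication of a chromosome 1 segment with 1 end at p1, so that B73, the heterozygote and P1-ww714 hold 2, 3 and 4 doses of the segment. The question was how gene expression follows dose inside the segment and what happens elsewhere. Library totals ran from 9486044 to 16189684 counts. The gene with the most counts in each of the 9 libraries was pdk1 (GRMZM2G306345), which encodes pyruvate phosphate dikinase of the C4 cycle, with 1.77% to 2.26% of the counts. The labels name separate samples but not separate plants, so the p-values measure the spread between these samples, which may be technical.

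The gene p1 (GRMZM2G084799) had 1, 0 and 1 counts in the B73 libraries, 2, 1 and 1 in the heterozygote and 4, 4 and 11 in P1-ww714. With 25 counts over 9 libraries it lay below the expression filter and was not tested, so it gives no check of the genotype labels at this depth.

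A run of 131 neighbouring tested genes on chromosome 1 that begins 2 genes before p1 was higher in P1-ww714 than in B73. Among the best expressed members with a name, sod4 (GRMZM2G169890), a cytosolic superoxide dismutase, rose from 89.4 ± 10.2 to 262.9 ± 23.9 CPM (SD, n = 3 per group). PhyB1 (GRMZM2G124532), a red light receptor, rose from 66.5 ± 6.67 to 137 ± 2.75 CPM, CaM1 (GRMZM2G152891), a calmodulin, from 119 ± 11.7 to 238 ± 10.8 CPM, and HAK8 (GRMZM2G173387), a potassium transporter, from 71.2 ± 5.69 to 136 ± 11.4 CPM. The log2 fold of sod4 was 1.56 with a standard error of 0.12, and that of PhyB1 was 1.04 with a standard error of 0.10. The fold changes were 2.94 for sod4, 2.06 for PhyB1, 1.99 for CaM1 and 1.91 for HAK8. The methionine sulfoxide reductase gene MSRB5.1 (GRMZM2G577677) rose 2.43-fold, les22 (GRMZM2G044074), of porphyrin synthesis, 2.14-fold, and DVR (GRMZM2G063048), of chlorophyll synthesis, 2.15-fold. The regulators GLK17 (GRMZM2G006477), ZBP14 (GRMZM2G018728), bZIP52 (GRMZM2G174284) and the Polycomb gene mez3 (GRMZM2G043484) rose 1.86-fold, 1.93-fold, 1.80-fold and 1.90-fold, and nad1 (GRMZM2G018941) rose 1.68-fold. Adjusted p-values of these 12 genes ran from 0.000232 to 0.03 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 22544 genes. The calls of 4 of these genes were lost without single libraries. For les22 the adjusted p was 0.0957 without B73 replicate 1, 0.109 without B73 replicate 3, 0.168 without P1-ww714 replicate 2 and 0.136 without P1-ww714 replicate 3. For nad1 it was 0.0756 and 0.0826 without B73 replicates 1 and 3 and 0.067 without P1-ww714 replicate 3, for mez3 0.0532 without B73 replicate 2, and for DVR 0.0509 without B73 replicate 1.

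Over the whole segment, 81 of the 131 genes rose in P1-ww714 against B73, 3 fell and 47 did not pass the test. The genes at alternating positions that did not set the bounds of the segment, 65 in number, had a median log2 fold of 0.91, which is a 1.88-fold increase, against an expectation of 1 from the doses. The bootstrap interval of this median over genes, which are not independent replicates, was 0.84 to 1.04. Of these 65 genes, 40 rose and 1 fell over all genes, and 53 rose and 1 fell adjusted over the list alone. The segment was found on these samples, so the count over all 131 genes is not independent evidence of direction. Over all 131 genes, those that set the bounds included, the median was 0.935 (bootstrap interval 0.888 to 0.994), below the expectation of 1. The median of segment genes simulated at full dose was 0.968. The camera test of the 65 genes gave p = 4.79e-147 with the preset correlation and p = 3.96e-07 with an estimated correlation. The 3 genes that fell were TPS8 (GRMZM2G038153), by 2.49 on the log2 scale, sus2 (GRMZM2G318780), a sucrose synthase gene, by 1.46, and GRMZM2G329040, by 0.78. These 3 were singled out after their values were seen.

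**Figure D1:**
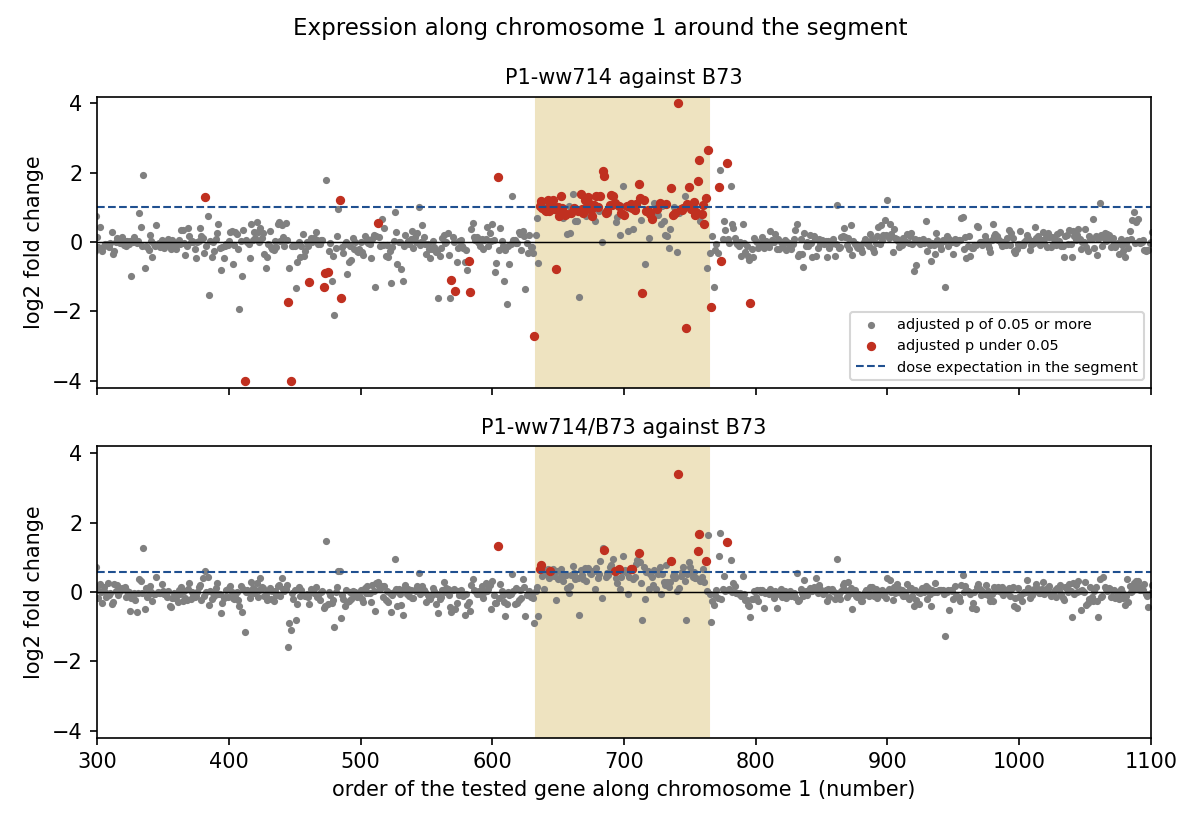
Log2 fold change of each tested gene (vertical axis) by its order along chromosome 1 (horizontal axis, numbers 300 to 1100) for P1-ww714 and P1-ww714/B73 against B73, with genes beyond 4 drawn at the edge. The shaded run of 131 genes holds the segment, the dashed line is the expectation from the doses, and red points passed an adjusted p of 0.05 (edgeR), 81 above 0 and 3 below within the segment in P1-ww714.

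In the heterozygote P1-ww714/B73, which addresses the 3-dose state, the same segment lay between the parents. The median of the 65 genes was 0.52 on the log2 scale (1.43-fold, bootstrap interval 0.41 to 0.60), with an expectation of 0.58. Over all 131 genes the median was 0.51 (bootstrap interval 0.449 to 0.57), below the expectation. Genes past the threshold over all genes were 14 of the 131, all higher, among them sod4 (1.88-fold, adjusted p = 0.0188) and MSRB5.1 (1.87-fold, adjusted p = 0.0109) in the edgeR test. PhyB1 had an adjusted p of 0.0516 at a 1.56-fold level and did not pass. Adjusted over the list alone, 45 of the 65 genes were higher and 1 was lower, and the camera p was 1.3e-06 with an estimated correlation. In simulated data with the doses of this design, 6.15% of segment genes were called in this comparison and 70% in P1-ww714 against B73. DESeq2 called 43 segment genes higher. Leaving out P1-ww714/B73 replicate 1 lowered the 14 calls by less than leaving out any other library, which left between 1 and 7.

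**Figure D2:**
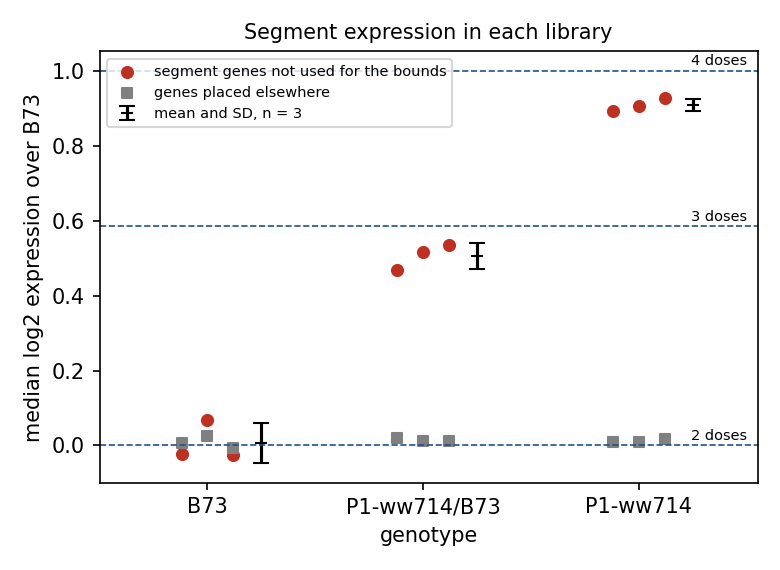
Median log2 expression over the B73 mean of the 65 segment genes not used for the bounds (circles) and of the genes placed elsewhere (squares) in each of the 9 libraries, by genotype, with the mean and SD of each group (n = 3) beside the circles and dashed lines at the levels of 2, 3 and 4 doses. The segment means were 0.01 ± 0.05 in B73, 0.51 ± 0.04 in P1-ww714/B73 and 0.91 ± 0.02 in P1-ww714. Each B73 library was set against the mean of the other B73 libraries, which widens the B73 SD.

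P1-ww714 against P1-ww714/B73 compares 4 with 3 doses. The median of the 65 segment genes was 0.41 on the log2 scale (1.33-fold, bootstrap interval 0.35 to 0.45), with an expectation of 0.41 from the doses. sod4 was at 1.57-fold and HAK8 at 1.43-fold, with adjusted p-values of 0.379 and 0.533. No gene of the genome passed the edgeR test in this comparison, while 680 had an unadjusted p under 0.05 and DESeq2 called 25. Adjusted over the list alone, 35 of the 65 genes were higher and 1 was lower, and the camera p was 1e-05 with an estimated correlation.

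Against the middle of the parents on the log2 scale, the 65 segment genes of the heterozygote lay at a median of 0.07 (bootstrap interval 0.04 to 0.10). Doses that add on the linear scale give 0.08 there. MSRB5.1 (0.26), les22 (0.25) and DVR (0.22) lay above the middle and HAK8 (-0.05) below it, and none of these passed the test. No gene of the genome departed from the middle past the edgeR threshold, 235 had an unadjusted p under 0.05, and DESeq2 called 2. The camera p of the 65 genes was 0.00467 with an estimated correlation.

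The 95% intervals of the single genes were set against the expectation from the doses and against 0. In P1-ww714 against B73, 91 of 131 intervals held the dose expectation and excluded 0, as for PhyB1, CaM1 and HAK8. For 12 genes the interval held 0 and excluded the dose expectation, for 3 it held both, and for 25 it excluded both, with 13 of these below the dose expectation and 12 above it. sod4 at 2.94-fold lay above and TPS8 and sus2 lay below. The 131 genes include the 66 that set the bounds by their folds in this comparison, so these counts are not independent of the search. In simulated data with the doses alone, 95.4% of intervals held the simulated fold, a larger share than here. In P1-ww714/B73 against B73 the same 4 classes held 81, 12, 24 and 14 genes, and in P1-ww714 against P1-ww714/B73 they held 80, 11, 33 and 7.

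**Figure D3:**
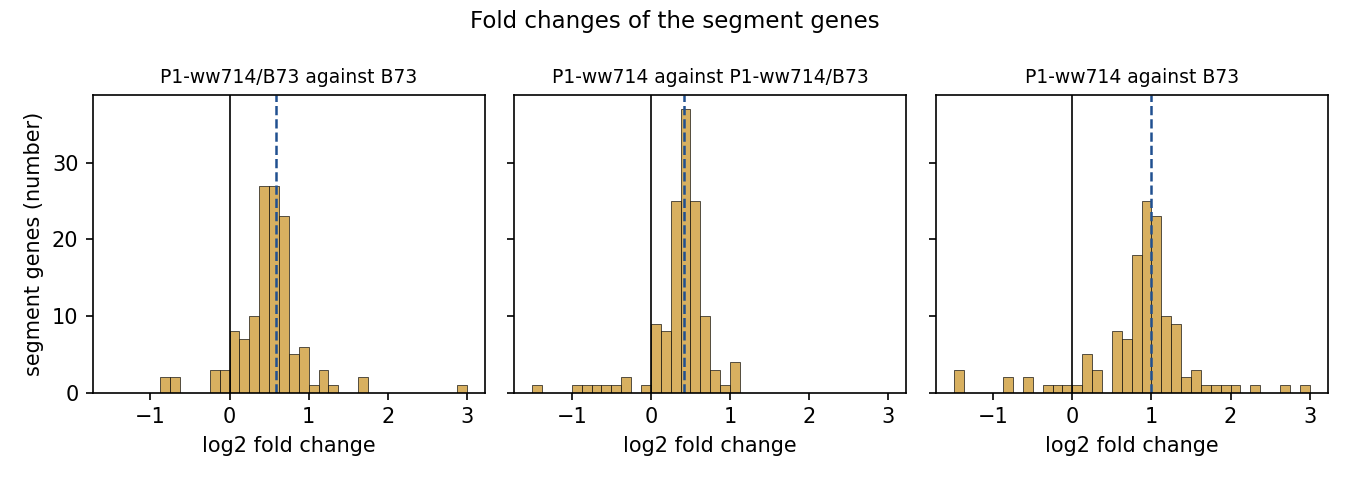
Number of the 131 segment genes (vertical axis) by log2 fold change (horizontal axis) in the 3 pairwise comparisons, with a solid line at 0 and a dashed line at the expectation from the doses, and genes beyond -1.5 or 3 drawn in the outermost bars. The medians over the 65 genes not used for the bounds were 0.52, 0.41 and 0.91 from the left panel to the right.

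Over the whole genome, 175 of 22544 tested genes changed in P1-ww714 against B73, 147 higher and 28 lower, and DESeq2 called 311, 221 higher and 90 lower. In P1-ww714/B73 against B73, 25 genes rose and 0 fell, and DESeq2 called 72, 71 higher and 1 lower. Of genes simulated at 2-fold and 4-fold in P1-ww714, this comparison called 1.49% and 51.5%. The 0 falls therefore do not show that no gene fell in the heterozygote. The allele trend, a straight line over 0, 1 and 2 alleles, gave 158 rising and 36 falling genes, and with DESeq2 253 and 112. All 25 genes of the heterozygote were also among those of P1-ww714, with the same direction. Independent lists of the 25 and 147 rising genes would share 0.163. In 10 simulations of unchanged groups set against the B73 libraries no gene passed the edgeR test, so calls could not overlap. By a rank chosen after this was seen, the 25 and 175 genes with the lowest p there shared 0 to 4 with the same direction (median 1), against 25 observed. The simulated groups were drawn around the means of the same B73 libraries, so the error of those means did not enter. The 0 to 4 are therefore not the overlap that shared controls alone would give. Both comparisons use the same 3 B73 libraries, so part of the observed overlap may come from the shared controls. Without single libraries, the 25 calls of the heterozygote fell to between 6 and 14, or by less without P1-ww714/B73 replicate 1. They ended at 0 when only both groups entered the fit.

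Outside the segment, 33 of 15572 placed genes changed in P1-ww714 against B73, 15 higher and 18 lower, and 23 of them lay on chromosome 1. PPCK1 (GRMZM2G178074), a kinase of phosphoenolpyruvate carboxylase that lies on chromosome 5, rose 2.94-fold from 8.53 ± 2.27 to 24.9 ± 7.82 CPM (SD, n = 3, edgeR adjusted p = 0.039). On chromosome 1, a gene named Txndc5 (GRMZM2G443655) fell by 1.45 on the log2 scale, from 30.4 ± 3.69 to 11.1 ± 0.615 CPM, saf1 (GRMZM2G042639) fell by 1.08, and GRMZM2G073628, with the same symbol Txndc5, fell by 0.54. Of genes without a symbol, GRMZM2G311165 fell by 4.33 on the log2 scale, from 86.3 ± 20.9 to 4.15 ± 6.81 CPM (SD, n = 3), with 4, 2 and 183 counts in the P1-ww714 libraries, and without P1-ww714 replicate 3 the log2 fold was -8.56. GRMZM2G123866 of chromosome 2 rose by 4.70 on that scale, from 0.432 ± 0.375 to 12.1 ± 0.838 CPM, with 8, 8 and 0 counts in the B73 libraries. The 300 tested genes before the segment held 17 calls, 13 of them lower, the 300 after it held 5, the rest of chromosome 1 held 1 and chromosomes 2 to 10 held 10. For windows, the placed genes outside the segment were set in order with the segment's genes left out. The fullest window of 100 such genes held 11 calls, against at most 6 in 10000 random orders (permutation p = 1e-04). No smaller p can come from these orders, and the window was not planned before the data were examined. The calls of this window lay on both sides of the segment, so they were not all neighbours. The longest run of calls in this order was 2 (permutation p = 0.07). The window held 7 calls without B73 replicate 2 and 7 without P1-ww714 replicate 2. The width of 300 genes was chosen after the data were seen. The calls of PPCK1 (adjusted p up to 0.208), saf1 (up to 0.0896), GRMZM2G073628 (up to 0.233) and GRMZM2G311165 (up to 0.168) were lost without some single libraries, and the 33 calls became 19 without B73 replicate 2, 16 without B73 replicate 3, 16 without P1-ww714 replicate 2 and 55 without P1-ww714/B73 replicate 1.

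In P1-ww714/B73 against B73, 3 placed genes outside the segment rose, namely GRMZM2G123866 by 3.84, GRMZM2G459563 by 1.45 and GRMZM2G110000 by 1.32 on the log2 scale, the last 2 being named after their values were seen. Only 1 of the 3 calls was left without B73 replicate 3, and likewise without P1-ww714/B73 replicate 3. Genes whose position is not given in the reference table held 58 calls in P1-ww714 against B73, 51 higher and 7 lower, of 6841 tested. GRMZM2G167698 rose from 0.652 ± 0.598 to 32.3 ± 18.5 CPM and GRMZM2G056743 from 0.346 ± 0.351 to 10.4 ± 2.94 CPM, while AC197387.3_FG004 fell from 6.83 ± 1.98 to 0.149 ± 0.258 CPM (SD, n = 3), with 7, 0 and 0 counts in the P1-ww714 libraries. The B73 libraries held 10, 14 and 0 counts of GRMZM2G167698 and 9, 4 and 0 of GRMZM2G056743, so the folds of both rest on few counts. The log2 fold of GRMZM2G167698 was 5.54, and 6.19 without B73 replicate 2. That of GRMZM2G056743 was 4.77, and 5.75 without B73 replicate 1. The rise of GRMZM2G167698 in P1-ww714/B73 against B73, of 4.32 on the log2 scale, lost its call without 6 of the 9 libraries in turn.

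Of 18 gene lists, 7 passed the camera threshold with the preset correlation in P1-ww714 against B73, all higher, and none passed with an estimated correlation or with fry (adjusted p of 0.552 or more). Heat shock genes had the lowest adjusted p (0.000229) with 13 of 14 members above 0 and a median log2 fold of 0.72, led by HSP90-1 (GRMZM2G024668, 9.44 to 26.6 CPM) and Hsp70 (GRMZM2G310431, 119 to 197 CPM). Benzoxazinoid genes, of a maize defence pathway, had 7 of 7 members above 0 with a median of 0.34 (adjusted p = 0.000687), nitrate genes 4 of 4 with 0.58 (adjusted p = 0.0113), and both had adjusted p = 0.756 with an estimated correlation, as did heat shock genes. Cell wall growth (median 0.14), defence (0.26), flavonoid and anthocyanin (0.32) and water channel genes (0.25) had adjusted p-values of 0.0189, 0.0189, 0.019 and 0.0299, and adjusted p = 0.767 with an estimated correlation. No list member passed the test over all genes. Adjusted over the list alone, 1 benzoxazinoid gene (bx2), 2 cell wall genes (expa1 and expB6), 1 nitrate gene (NNR1), 1 glutathione transferase gene (GST39) and 3 jasmonate repressor genes (TIFY28, TIFY20 and TIFY4) passed, all higher. In the single libraries the heat shock median stood at 0.97 in P1-ww714 replicate 3 against 0.26 and 0.19 in replicates 1 and 2, and that library also stood apart for nitrate (1.12 against 0.11 and 0.11), flavonoid and anthocyanin (0.76 against 0.06 and 0.20) and water channel genes (0.47 against 0.04 and -0.003). Without it only heat shock (median 0.23) and benzoxazinoid genes (0.21) passed, each with adjusted p = 0.0438, and the medians of nitrate (0.10, adjusted p = 0.263), flavonoid (0.10, 0.404), water channel (0.05, 0.614), cell wall (0.10, 0.188) and defence genes (0.30, 0.0825) did not. Without B73 replicate 3 only heat shock, benzoxazinoid and nitrate genes passed, without B73 replicate 2 cell wall (adjusted p = 0.105) and water channel genes (0.0604) did not, and without P1-ww714 replicate 1 there were 11 lists.

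In P1-ww714/B73 against B73, 6 lists passed with the preset correlation. Cell division genes (median -0.19, adjusted p = 0.000605), histone genes (-0.25, adjusted p = 0.0217) and auxin genes (-0.04, adjusted p = 0.038) were lower, and C4 cycle and Rubisco (0.14), heat shock (0.26) and nitrate genes (0.29), each with adjusted p = 0.038, were higher. None held with an estimated correlation (adjusted p = 0.859 for each of the 6). P1-ww714/B73 replicate 1 stood apart from the other libraries, with a mean correlation of 0.965 with them against 0.974 to 0.982 for the rest, and its histone median was -1.84 over B73, against 0.29 and -0.19 in replicates 2 and 3, and its cell division median -1.08, against 0.02 and 0.04. Without it, the medians were 0.09 for histone genes and 0.03 for cell division genes (adjusted p = 0.395 for both) and 2 lists passed. The histone list also failed without B73 replicate 1 (-0.07, adjusted p = 0.319), and the auxin, heat shock and nitrate lists failed without 4 of the 9 libraries in turn and the C4 cycle and Rubisco list without 3. No list member passed the test over all genes or adjusted over the list alone in this comparison.

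In P1-ww714 against P1-ww714/B73, 9 lists passed with the preset correlation and none with an estimated correlation (adjusted p of 0.605 to 0.625). Histone (median 0.29), cell division (0.18), glutathione transferase (0.17), defence (0.37), benzoxazinoid (0.27), heat shock (0.31), flavonoid (0.16) and cell wall genes (0.12) were higher and C4 cycle and Rubisco genes (-0.11) lower. Without P1-ww714/B73 replicate 1 the median was -0.10 for cell division genes (adjusted p = 0.0135) and 0.07 for histone genes (adjusted p = 0.789). Medians also turned for C4 cycle and Rubisco genes without P1-ww714 replicate 1 (0.02) and for cell wall (-0.01) and flavonoid genes (-0.01) without P1-ww714 replicate 3, and each of the 9 lists failed the threshold without at least 1 library. Against the middle of the parents, 5 lists passed with the preset correlation and none with an estimated correlation (adjusted p = 0.837 for each), with histone (-0.27), cell division (-0.22), defence (-0.12) and glutathione transferase genes (-0.04) lower and C4 cycle and Rubisco genes (0.12) higher. Without P1-ww714/B73 replicate 1 the medians were 0.01 for histone genes (adjusted p = 0.786) and 0.04 for cell division genes (adjusted p = 0.0409), and without P1-ww714/B73 replicate 3 that of glutathione transferase genes was 0.008 (adjusted p = 0.869). The defence list failed without 5 of the 9 libraries in turn and the C4 cycle and Rubisco list without 4. No list member passed adjusted over the list alone in either comparison. Auxin, cytokinin, ribosomal protein, flowering and clock, light harvesting, oxylipin and jasmonate, and small RNA genes passed in none of these 2 comparisons or P1-ww714 against B73, and their medians in P1-ww714 against B73 were -0.04, -0.02, 0.06, -0.17, 0.14, 0.06 and -0.07. The seed protein list had 1 tested member, GLB1 (log2 fold 0.30), and the root protein list 2, ZmCASPL5A1 (-0.26) and rth3 (0.20), so neither was tested.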

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

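The segment medians kept their direction and their side of the threshold under every alternative run, with 0.89 to 0.96 in P1-ww714 against B73, 0.46 to 0.53 in P1-ww714/B73 against B73 and 0.37 to 0.41 in P1-ww714 against P1-ww714/B73 when libraries were left out. The normalization, filter and bounds alternatives moved no count of calls by over 1.5 times. The alternatives chosen after seeing the data were TMM without the segment for gene counts, an estimated correlation for the segment, DESeq2 for the segment calls, leaving out libraries for the lists, and the window alternatives. Unless stated, the cause of a change was not tested. DESeq2 gave 311 genes in P1-ww714 against B73, 72 in P1-ww714/B73 against B73, 25 in P1-ww714 against P1-ww714/B73, 2 against the mid-parent, 365 in the allele trend and 43 segment genes higher in the heterozygote. With only both groups in the fit, P1-ww714/B73 against B73 gave 0 genes, with fewer libraries to estimate the spread. At a threshold of 0.01 the placed genes outside the segment were 16 in P1-ww714 against B73 and 1 in P1-ww714/B73 against B73. The other counts outside the segment given here are also of placed genes. With the replicate block the allele trend gave 295 genes, the heterozygote 8 segment genes and P1-ww714 against B73 243 genes, 159 higher and 84 lower. Of these 243 genes, 88 lay in the segment and 78 were placed elsewhere. The replicate numbers shared between groups were not taken as pairs, since the labels name no shared batch. A further reason was that correlations of same-numbered libraries ran from -0.12 to 0.50. However, 5 of 9 libraries correlated best with their own number. A grouping by replicate number also gave 51 genes in the mid-parent comparison, so structure shared by some same-numbered libraries is not excluded. With an estimated correlation 0 lists passed in each of the 4 comparisons. Leaving out single libraries gave 6 to 20 genes in P1-ww714/B73 against B73, 0 to 4 in P1-ww714 against P1-ww714/B73, 1 to 10 segment genes in the heterozygote, 16 to 55 and 1 to 3 genes outside the segment in P1-ww714 and P1-ww714/B73 against B73, and 0 to 3 outside it between P1-ww714 and P1-ww714/B73. The lists that passed numbered 2 to 11 in P1-ww714 against B73, 2 to 8 in P1-ww714/B73 against B73, 5 to 10 in P1-ww714 against P1-ww714/B73 and 2 to 9 against the mid-parent when libraries were left out. Some list medians reversed when 1 library was left out, and their ranges over the libraries left out follow. In P1-ww714/B73 against B73 they were -0.402 to 0.027 for cell division and -0.696 to 0.088 for histones, in P1-ww714 against P1-ww714/B73 -0.097 to 0.394 for cell division, and against the mid-parent -0.332 to 0.037 for cell division and -0.698 to 0.008 for histones, each with its reversed end without P1-ww714/B73 replicate 1. In P1-ww714 against P1-ww714/B73 they were -0.234 to 0.017 for C4 cycle and Rubisco (reversed without P1-ww714 replicate 1), -0.011 to 0.213 for cell wall growth and -0.012 to 0.324 for flavonoid genes (both reversed without P1-ww714 replicate 3). Against the mid-parent, glutathione transferases gave -0.197 to 0.008, reversed without P1-ww714/B73 replicate 3. For the named genes, 220 of 264 alternatives kept the call, 44 lost it and 0 reversed. Depth limits p1, with 25 counts in all libraries.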

Other observations

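Of the tests in this part, the counts over other splits of the libraries were planned before their results were seen, except that the number of drawn splits of the 9 libraries was raised after a smaller draw had been seen, and the others were chosen after the result they bear on was seen.

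Genes called on chromosome 1 beside the segment form a pattern of their own. All counts here come from the fit without the replicate block. With the block, more placed genes were called outside the segment. Of placed genes outside the segment, 23 of 2367 on chromosome 1 and 10 of 13205 on chromosomes 2 to 10 were called in P1-ww714 against B73 (Fisher's exact test, p = 2.71e-12, odds ratio 12.9), which argues against a response spread evenly over the genome as the source of the chromosome 1 calls and leaves the 10 others open. Loss of reads from non-B73 alleles on the reference may account for the 16 falls beside the segment, such as that of saf1, since the heterozygote reached a median share of 0.551 of their change (bootstrap interval 0.482 to 0.600) and such loss gives 0.5. The 11 calls placed elsewhere gave 0.439 (0.382 to 0.536), so this share does not single out that explanation, which in any case does not give the 6 flanking genes that rose, such as GRMZM2G110000 and GRMZM2G459563. A chromosome around P1-ww714 that differs from B73 in the regulation of its genes stays open and was not tested, since no sequence variants were used here.

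Genes without a given position held 58 calls of 6841 tested, and placed genes 117 of 15703. A hypothesis is that the same share of them lies in the segment. The called share did not differ detectably from that of all placed genes (58 calls against 51.0 expected, Fisher's exact test, p = 0.41). It exceeded that of placed genes elsewhere (14.5 expected, Fisher's exact test, p = 1.04e-10). Both go with the hypothesis but do not decide it, since another source of calls among unplaced genes could give the same share. Dose alone is argued against as the only source of the 51 rises. Intervals of 26 of the 51 held a log2 fold of 1, against 67 of the 81 in the segment (Fisher's exact test, p = 0.000163). The test pools intervals above 1, such as that of GRMZM2G167698 at 46.6-fold, with intervals below 1. An example below 1 is GRMZM2G135968 (log2 fold 0.72, standard error 0.102). The test therefore does not single out the largest rises. Segment genes were also chosen by their folds in this comparison. What sets rises larger than dose was not tested.

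The low medians of histone and cell division genes in P1-ww714/B73 against B73, which did not pass with an estimated correlation (adjusted p = 0.859 for both lists), may come from 1 library. P1-ww714/B73 replicate 1 stood at -1.84 and -1.08 over B73, the other libraries of the heterozygote at 0.29 and -0.19 for histone and 0.02 and 0.04 for cell division genes, and without replicate 1, 0 of both lists passed the threshold with a median below 0. Its total of 11504948 counts lies between those of the other libraries, which argues against sequencing depth. P1-ww714/B73 replicate 1 was also low for cytosolic ribosomal protein genes (-0.568, against 0.462 and 0.074 in replicates 2 and 3). Its shift was thus not limited to both lists. Whether that seedling sample held fewer dividing cells stays open, since no value here tells it apart from a difference in sampling.

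The heterozygote of the segment lay above the middle of the parents on the log2 scale. A hypothesis is that doses add on the linear scale, which gives 0.08. The median was 0.07, and its bootstrap interval over genes of 0.04 to 0.10 held 0.08 and excluded 0. All these genes were measured in the same 9 libraries, so the interval leaves out the spread between libraries. The segment median had an SD of 0.053 over the B73 libraries, 0.035 over P1-ww714/B73 and 0.016 over P1-ww714. Each B73 library was set against the mean of the other B73 libraries. This widens the B73 SD, which is therefore not comparable with the others. The interval alone does not settle whether the departure differs from 0.

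Other splits of the libraries bear on the counts of calls. With 10 splits of 6 libraries a share under 0.05 cannot be had. The segment was set on the real grouping and was not searched anew in other splits, so counts within it favour the real grouping. The real split was 1 of 10 with as many genes for P1-ww714 against B73 (175 genes, 0 at most in the others), for P1-ww714/B73 against B73 (25 and 0), for genes outside the segment in P1-ww714 against B73 (33 and 0), and for segment genes higher in P1-ww714 and P1-ww714/B73 against B73 (81 and 0, 14 and 0). A count of 0 is reached by any split, so the splits decide nothing for P1-ww714 against P1-ww714/B73 (0 genes, reached by all 10 splits, 0 at most in the others) or for the mid-parent (0 genes, reached by all 100 drawn splits of the 9 libraries, 133 at most in the others). The split with 133 genes kept the 3 genotypes apart and set P1-ww714 against the mean of the other genotypes, with 67 segment genes higher. The next highest, with 51 genes and 0 higher in the segment, grouped the libraries by replicate number, which points to a structure that some same-numbered libraries share, though not every pair of them deviated together. For the allele trend, 1 of 100 drawn splits of the 9 libraries, the real one, reached 194 genes and the highest other gave 6. This argues against a chance assignment of these libraries. The labels do not name separate plants, so chance differences between the sources of each genotype are not excluded. For the gene lists at the preset correlation, 7 of 10 splits gave as many as the 7 of P1-ww714 against B73 (12 at most in the others), 8 of 10 as many as the 6 of P1-ww714/B73 against B73 (10 at most), and 6 of 10 as many as the 9 of P1-ww714 against P1-ww714/B73 (12 at most). Chance cannot be excluded for the 5 lists against the mid-parent, which 95 of 100 splits matched or exceeded (13 at most).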
